A study of Mus musculus with 24 samples.

How the data were processed

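Liver transcripts were measured on 24 Affymetrix mouse expression arrays, a 1-colour platform on which each probe set reports the signal of a transcript. Per the labels' protocols, total RNA of male BALB/c mice was copied to cDNA from an oligo(dT) primer, transcribed into biotin-labelled cRNA and hybridised. The deposited table holds a linear intensity for each of 45101 probe sets on each array. The method that summarised probes into probe sets, the background correction and any scaling by the authors are not given in the sources used here. The values showed no common scale, with array medians from 9.47 to 18.0, so the absolute scale stays unknown and only differences between arrays scaled alike were used. The deposited table gave no detection calls and no scan dates, so neither a test of signal above background nor a test of scan batches was made.

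Probe sets were named from the platform's gene annotation in the Gene Expression Omnibus, which can be old. It paired 34945 probe sets with 1 gene and 932 with several, and it listed none for 9160. Probe sets with several genes or none were not named or tested as genes. The Entrez identifiers of 34741 of the single-gene probe sets were found in the RefSeq table of the GRCm38.p6 assembly, which changed 0 symbols, and no coordinates were taken from it because the build behind the array annotation is not given. Control probe sets (64) were left out of all tests of genes. For the array checks, 24 poly-A control and 18 hybridisation control probe sets were used.

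Arrays were first compared with each other, since the labels describe 6 mice per diet. Over 1463 genes with a mean log2 signal above 9, the SD of the log2 difference was computed for each of the 276 pairs of arrays. Pairs with an SD under 0.08 were taken as repeat hybridisations of 1 labelled RNA, and their log2 values were averaged. The resulting sets were then compared on a fingerprint of the 200 most variable genes with a mean log2 signal above 7. A fingerprint distance under 1.2 times that of the remaining genes was read as 1 RNA labelled more than once, and those sets were averaged too. Both thresholds were chosen after seeing the data. RNA that carried the labels of 2 diets (0.1% replicates 1, 3 and 6 together with 1.0% replicate 1) entered no comparison. The fit therefore held 11 RNA samples (4 control, 3 at 0.1%, 2 at 0.5% and 2 at 1.0%) in place of the 24 livers planned, and quantile normalization, planned as an alternative, became the setting used because the arrays were on different scales.

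Signals were quantile-normalized between arrays, floored at 8 and log2-transformed, so that 3.00 on the log2 scale is the floor. The floor held 5.16% of the values of the genes tested. The lowest 40% of probe sets by mean were left out, which kept 27022, and each gene was represented by its probe set with the highest mean, which gave 13068 genes. Each comparison was tested in limma 3.58.1 under R 4.3.3 with lmFit and eBayes (trend = TRUE), in 1 fit over the 4 diets with 7 residual degrees of freedom and no covariate. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 13068 genes, and a gene was called at an adjusted p under 0.05. The same fit gave the differences between doses, an F-test over the diets and, in a second model, a slope on the percent of phloridzin in the diet. All printed fold changes are on this floored log2 scale, which understates the change of dim transcripts.

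Before the data were examined, the comparisons, the tests, the rule for named genes, 34 gene lists and a first set of alternatives were fixed. The lists cover gluconeogenesis, glycolysis and glucose entry, glycogen, the fasting and FOXO response, fatty acid synthesis, cholesterol synthesis, PPARA fatty acid oxidation, bile acid and sterol transport, xenobiotic response (CAR/PXR and AhR), NRF2, amino acid catabolism and urea cycle, unfolded protein and ATF4 response, heat shock chaperones, acute phase response, interferon response, cell cycle, circadian clock, immediate early response, male-biased and female-biased liver genes, periportal and pericentral hepatocyte genes, and markers of 11 other cell types. Lists with 5 or more measured members (31) were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 31 lists. Camera with an estimated correlation and fry were run beside it. The marker lists of pancreatic acinar cells, adipocytes and skeletal muscle had 3, 3 and 2 measured members and were not tested. A list's score in a sample is the mean of its members' log2 values minus the control mean.

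Named genes were, for each comparison against control, up to 8 rises and 8 falls with the largest change among called genes; up to 4 members of each list in order of p at 1.0%; a panel of 16 metabolic and clock genes; and the 6 genes with the lowest p for the dose slope. Bmal1 is listed by the platform as Arntl. List members outside this rule, named because they passed the adjustment over their list alone, and Nsd3 were chosen after their values were seen. Among 60 named genes with more than 1 probe set above the filter, 18 had probe sets of opposite sign at 1.0% against control.

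The 3' and 5' control probe sets of Gapdh and beta-actin and the ratio of poly-A to hybridisation control transcripts were computed per array, and each dose was set against control with a two-sided exact permutation test. Correlations of fold changes between doses share the control samples, so 100 simulated pairs of unchanged groups against shared controls and all 6 splits of the controls into 2 and 2 were computed beside them. The scripts were tested on simulated data in which 200 of 13068 genes were changed by known amounts at the real sample numbers. At 0.1% against control, 53.6% of the genes changed by 1 on the log2 scale and 95.6% of those changed by 2 were recovered, with 13 false calls. At 0.5% these shares were 37.7% and 95.6%, with 2 false calls, and at 1.0% they were 40.6% and 86.8%, with 5. Changes of 0.5 were recovered in 7.94%, 4.76% and 1.59% of cases at the 3 doses. At 0.1% the genes recovered numbered 5, 37 and 65 for changes of 0.5, 1 and 2. They numbered 3, 26 and 65 at 0.5%, and 1, 28 and 59 at 1.0%. False calls were thus a larger share of calls at 0.1% than at the other doses. That share was above the level at which the adjusted p threshold aims. How far these counts vary between simulations was not tested.

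Alternatives covered scaling, floor, filter, choice of probe sets, variance model, array weights, threshold, samples in the fit, dose scale, the handling of repeat arrays, replicate number as a block and leaving out each sample in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.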

Results

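Phloridzin, a glucoside found in apple that blocks sodium-glucose cotransport, was fed to male BALB/c mice at 0.1, 0.5 or 1.0% of a purified diet for 14 days, and liver transcripts were measured on 24 arrays. The labels describe 4 diets, including a control diet without phloridzin, with 6 mice per diet housed 3 to a cage. The series title asks how phloridzin affects blood glucose and hepatic gene expression; blood glucose itself was not analysed here. The number of separate RNA samples, which was lower than that of arrays, limits the precision of every value below.

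The 24 arrays did not behave as 24 separate RNA samples. In 13 pairs of arrays the SD of the log2 difference over 1463 well measured genes was 0.0436 to 0.0577, against 0.164 or more in 255 other pairs, and 18 of the 24 arrays fell into 8 such repeat sets. A further 8 pairs, at 0.108 to 0.137, matched in the most variable genes and were read as 1 RNA labelled more than once. The 2 joins this made had fingerprint ratios of 0.973 and 1.09, and the next lowest, 1.29 and 1.39, were between 0.5% replicates 4 and 5 and 1.0% arrays. The threshold between them was chosen after seeing the data and sets the sample numbers at 0.5% and 1.0%. Arrays of 1 RNA were averaged and counted once, which left 4 control samples (replicates 1 and 3, 2 and 4, 5, and 6), 3 at 0.1% (replicates 2, 4 and 5), 2 at 0.5% (replicates 1, 2, 3 and 6, and 4 and 5) and 2 at 1.0% (replicates 2, 3, 5 and 6, and 4). Replicates 1, 3 and 6 at 0.1% and replicate 1 at 1.0% were near-identical although their labels name different diets, and their RNA entered no comparison. Whether the 11 remaining samples are 11 separate mice is not known, so p-values measure the spread between these samples.

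**Figure D1:**
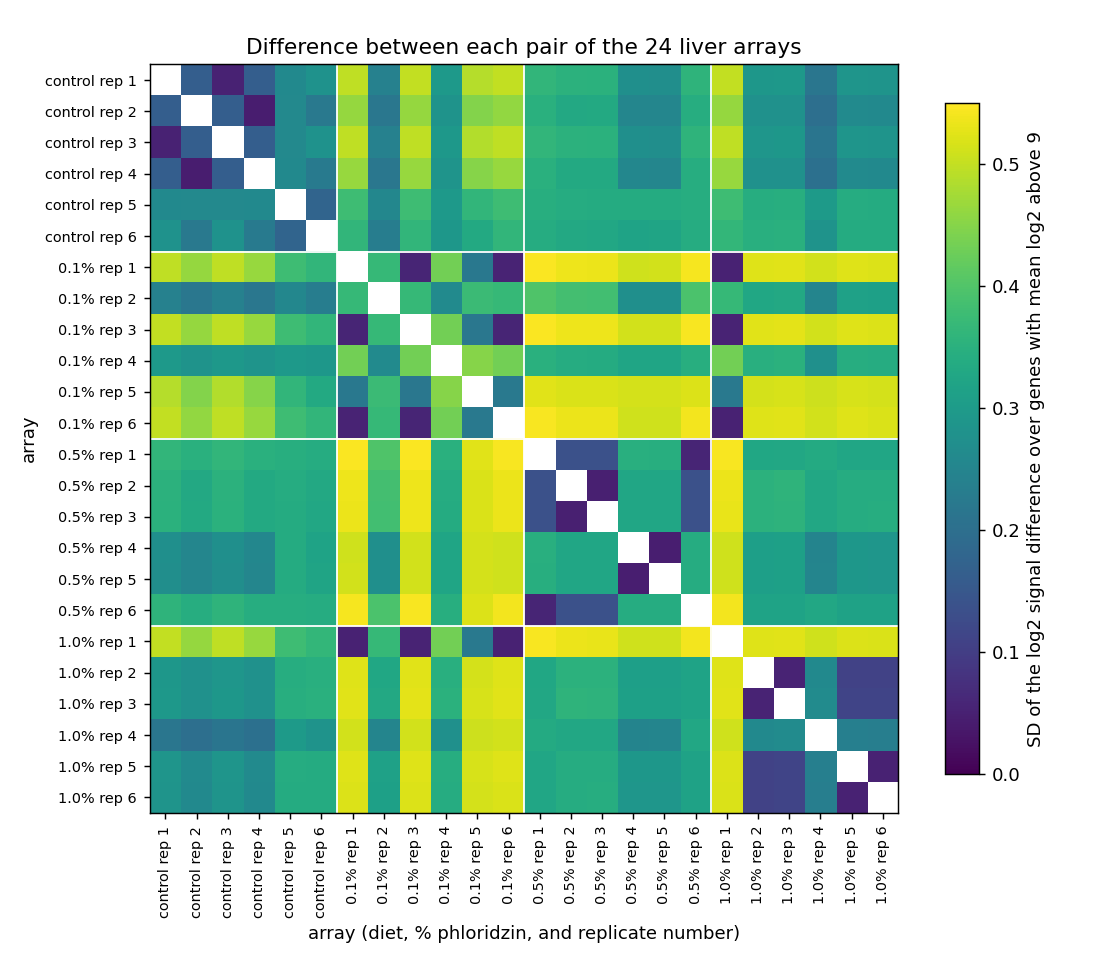
Each square gives the SD of the log2 signal difference between 2 of the 24 arrays, over genes with a mean log2 signal above 9, with white lines between diets. The darkest squares, at 0.0436 to 0.0577, are the repeat pairs, and they include replicate 1 at 1.0% with replicates 1, 3 and 6 at 0.1%.

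At 0.1% phloridzin, Dusp1, a phosphatase that inactivates MAP kinases, fell from a log2 signal of 10.40 ± 0.26 (SD, n = 4) in control liver to 9.04 ± 0.13 (SD, n = 3), a 2.56-fold fall (limma adjusted p = 0.0148). Zfp36l1, which promotes the decay of AU-rich mRNAs, fell from 11.02 ± 0.11 to 10.37 ± 0.08 (adjusted p = 0.0395). Gsk3a, a kinase that inhibits glycogen synthase, rose 1.91-fold, from 7.91 ± 0.19 to 8.84 ± 0.18 (adjusted p = 0.0395). These were the 3 genes called among 13068, beside 1104 (8.45%) with an unadjusted p under 0.05. The Dusp1 call was lost without 0.1% replicate 2, 4 or 5 (adjusted p up to 0.0804) and under 5 of 16 other settings (up to 0.217). The Gsk3a call was lost in 10 of the 11 runs that left out a sample (kept only without control replicate 5; adjusted p up to 0.192), and that of Zfp36l1 in all 11 (up to 0.180). Of the 16 other settings, 8 ended the Gsk3a call and 9 the Zfp36l1 call (adjusted p up to 0.822 for both).

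Genes of fatty acid synthesis rose as a group at 0.1%. Of 20 measured members 16 were higher, with a median log2 change of 0.30 (camera adjusted p = 3.6e-05), against an adjusted p = 0.84 with an estimated correlation. Across all alternatives that p ran from 4.3e-08 to 0.84. None of the members was called over all genes, and 3 rose when adjusted over the list alone: Acacb (0.68 ± 0.21, log2 change ± SE), which makes malonyl-CoA, the desaturase Scd1 (0.40 ± 0.11) and the acetyl-CoA synthetase Acss2 (0.69 ± 0.18). Fasn, the fatty acid synthase, stood at 0.38 ± 0.22, not past a threshold, and Acly at 0.46 ± 0.16, with its 3 other probe sets at 0.10, -0.25 and -0.22. Cholesterol synthesis genes also rose as a group, with 18 of 20 members higher and a median of 0.13 (camera adjusted p = 0.0132; adjusted p = 0.84 with an estimated correlation; 1.3e-06 to 0.84 across alternatives), and 0 members were called or rose when adjusted over the list alone. Examples were Sqle at 0.74 ± 0.34 and Dhcr7 at 0.50 ± 0.20. List scores in 0.1% replicates 2, 4 and 5 were 0.09, 0.10 and 0.43 for cholesterol synthesis, against -0.22 to 0.38 in control samples. For fatty acid synthesis they were 0.33, 0.27 and 0.17, against -0.22 to 0.21. The cholesterol call was lost without control replicates 1 and 3 (adjusted p = 0.121), control replicate 5 (0.350) or 0.1% replicate 5 (0.297), without scaling and with all 24 arrays.

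Markers of Kupffer cells, the resident macrophages of the liver, fell as a group at 0.1%, with 10 of 13 lower and a median of -0.18 (camera adjusted p = 0.0188; adjusted p = 0.84 with an estimated correlation; 0.00011 to 0.84 across alternatives). Over all genes 0 members were called, while Vsig4 (-0.42 ± 0.12), a complement receptor, and Cd163 (-0.81 ± 0.17), a haemoglobin scavenger receptor, fell when adjusted over the list alone. The sample of 0.1% replicate 4 had the lowest Kupffer score, at -0.40, and the lowest score for sinusoidal endothelial markers, at -0.43. Its actin 3' signal exceeded the 5' signal by 2.30 on the log2 scale against 1.40 ± 0.08 in control liver. The Kupffer call was lost without that sample (adjusted p = 0.636) and without control replicates 2 and 4 (0.0970). The 3' minus 5' difference of Gapdh, a sign of RNA quality, was -0.34 ± 0.04 in control liver and -0.19 ± 0.13 at 0.1% (exact permutation p = 0.0286, the smallest that 35 splits allow). The first 2 principal components, with 25.6% and 13.3% of the variance, set 0.1% replicate 5 and 0.1% replicate 4 apart from the other samples.

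At 0.5% phloridzin, acute phase genes, which the liver secretes during inflammation, rose as a group, with 19 of 25 measured members higher and a median log2 change of 0.28 (camera adjusted p = 2.1e-09; adjusted p = 0.41 with an estimated correlation; 9.5e-24 to 0.41 across alternatives). No member was called over all genes, and 9 rose when adjusted over the list alone: Saa1, Saa2, Orm1, Orm2, Lcn2, Apcs, Itih4, Mt1 and Mt2. The Saa2 probe set is marked x, a class dropped in an alternative below. Whether it also reads Saa1 was not tested, so the 9 may not be independent. Saa2, a serum amyloid A, stood at 7.90 ± 0.43 (SD, n = 4) in control liver and 11.57 ± 2.02 (SD, n = 2) at 0.5%, with the lower of the 2 values, 10.15, in the RNA of replicates 4 and 5; it was not called over all genes (adjusted p = 0.41). Orm2, an acid glycoprotein, was 2.98 ± 0.63 higher and Lcn2, a siderophore binder, 2.25 ± 0.66 higher (log2 change ± SE). The call was lost without replicates 1, 2, 3 and 6 (adjusted p = 0.0766). In the RNA of replicates 1, 2, 3 and 6 the mean of 6 clock output transcripts, chosen after their values were seen, lay at -2.18 relative to control, where control samples ran from -0.51 to 0.39, and Dbp, a clock-driven transcription factor, stood at 5.24 against 8.82 ± 1.21 in control liver. Markers of neutrophils rose as a group, with 7 of 9 higher and a median of 0.48 (camera adjusted p = 0.0109; adjusted p = 0.43 with an estimated correlation; 2.1e-05 to 0.89 across alternatives). That median is the change of Elane, a dim transcript with a mean log2 signal of 3.63. Ltf (3.01) and Mmp8 (3.02) also lay near the floor of 3.00, against 6.01 for S100a8. No neutrophil marker passed over all genes or when adjusted over the list alone, S100a8 stood at 0.97 ± 0.38, and the score was 0.79 in the RNA of replicates 4 and 5 and 0.10 in the other sample. That call was lost without replicates 4 and 5 (adjusted p = 0.887). It was also lost without the joining of RNA by fingerprint (0.0828 with 13 samples), with 15 samples, which also adds the RNA with labels of different diets under both (0.0772), and with all 24 arrays (0.0941).

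Genes of amino acid catabolism and the urea cycle fell as a group at 0.5%, with 20 of 25 lower and a median of -0.13 (camera adjusted p = 0.000345; adjusted p = 0.41 with an estimated correlation; 2.2e-06 to 0.41 across alternatives). None was called over all genes, and Tat (-0.49 ± 0.13), which degrades tyrosine, and Cth (-0.34 ± 0.10), which makes cysteine, fell when adjusted over the list alone. The list's score was -0.19 in replicates 1, 2, 3 and 6, the RNA with low clock output. In replicates 4 and 5 it was -0.06, within the control range of -0.10 to 0.10. Genes of the NRF2 antioxidant response fell as a group, with 15 of 22 lower and a median of -0.13 (camera adjusted p = 0.00398; adjusted p = 0.41 with an estimated correlation; 0.00047 to 0.41 across alternatives). None of these was called over all genes, and the glutathione transferases Gsta2 (-0.50 ± 0.16), Gstm1 (-0.43 ± 0.10), Gstm2 (-0.73 ± 0.13) and Gstm6 (-0.52 ± 0.12) fell when adjusted over the list alone. Both calls were lost without the RNA of replicates 1, 2, 3 and 6 (adjusted p = 0.295 and 0.0766). Bile acid genes did not shift as a group (camera adjusted p = 0.537), but when adjusted over the list alone Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose (2.10 ± 0.50) and Nr0b2, a repressor of Cyp7a1, fell (-0.90 ± 0.21), as did Cyp7b1 and Abcg8. Over all genes their adjusted p was 0.46 for Cyp7a1 and 0.45 for Nr0b2.

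Rbmxl2, an RNA-binding protein known from germ cells, was the 1 gene called at 0.5% (adjusted p = 0.0491), beside 684 genes with an unadjusted p under 0.05. It fell from 5.09 ± 0.41 (SD, n = 4) to the floor of 3.00 in both samples, so the fall was at least 4.27-fold. The transcript was dim in control liver too, and its log2 change ran from -3.10 to -0.23 over the alternatives, the smallest with a higher floor. The Rbmxl2 call was kept only without control replicate 5 or 0.1% replicate 5 among the 11 runs that left out a sample (adjusted p up to 0.230) and was lost under 6 of 15 other settings (up to 0.835), and the count of called genes was 8 without 0.5% replicates 4 and 5 and 17 without the joining of RNA by fingerprint (13 samples). At 0.5% the Gapdh 3' minus 5' difference was -0.17 ± 0.01 and that of actin 1.62 ± 0.13, each with an exact permutation p of 0.0667 against control, the smallest that 15 splits allow.

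**Figure D2:**
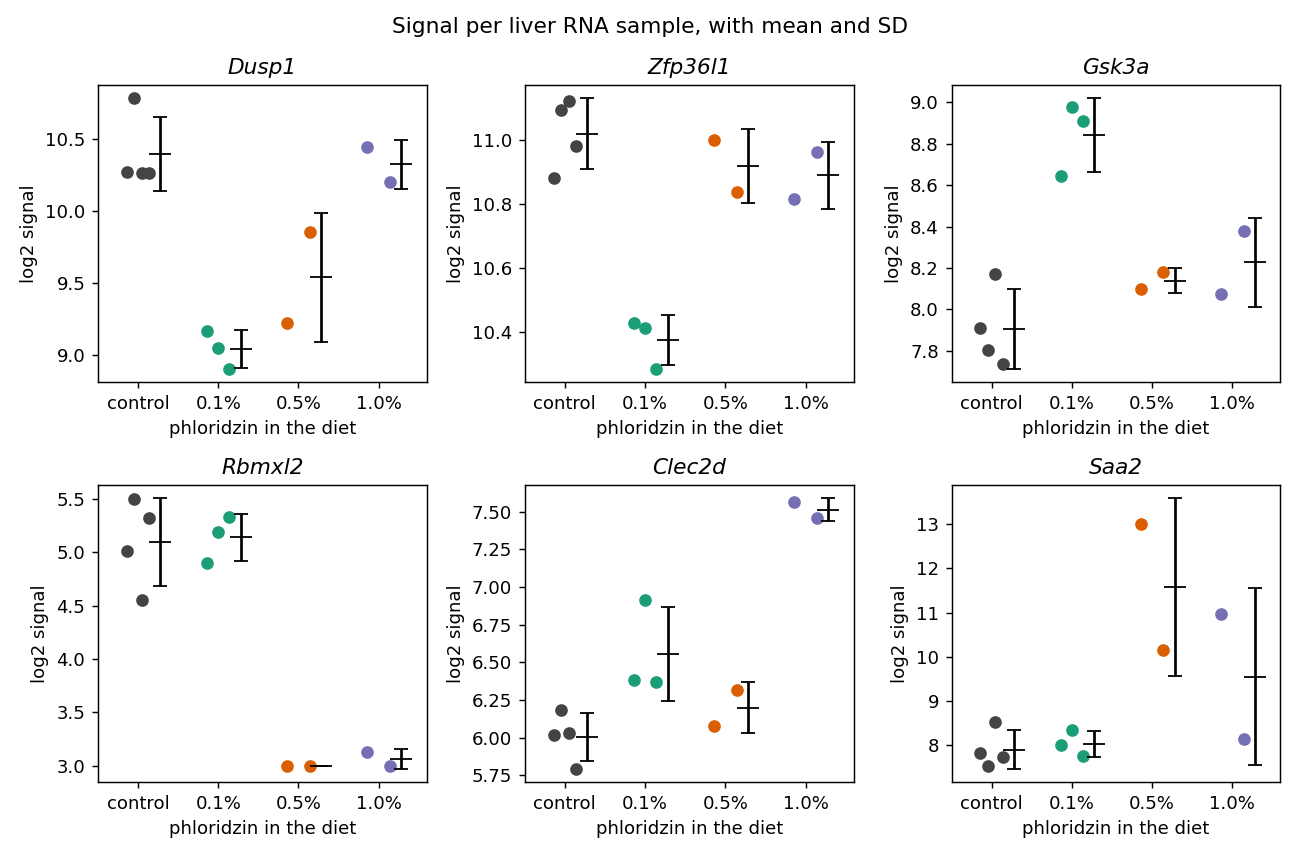
Points are the normalized log2 signals of single RNA samples at each phloridzin content of the diet, with the mean and SD beside them, for 5 called genes and Saa2; the vertical ranges differ between panels and 3.00 is the floor. Dusp1 and Zfp36l1 lay lower and Gsk3a higher at 0.1% than in control liver, and both Saa2 values at 0.5% lay above every control value.

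At 1.0% phloridzin, genes of cholesterol synthesis rose as a group, with 18 of 20 higher and a median log2 change of 0.17 (camera adjusted p = 0.000239; adjusted p = 0.66 with an estimated correlation; 1.6e-10 to 0.84 across alternatives). None was called over all genes or when adjusted over the list alone. Stard4, a sterol carrier, stood at 0.71 ± 0.20, Sqle, squalene epoxidase, at 0.91 ± 0.39 and Dhcr7 at 0.55 ± 0.23. The cholesterol score was 0.25 in replicates 2, 3, 5 and 6 and 0.33 in replicate 4. Both lay within the control range of -0.22 to 0.38. Genes of fatty acid synthesis rose by a median of 0.09, with 15 of 20 higher (camera adjusted p = 0.0400; adjusted p = 0.66 with an estimated correlation; 0.0016 to 0.84 across alternatives), and again none passed over all genes or when adjusted over the list alone. Acacb stood at 0.63 ± 0.23 and Acly at 0.41 ± 0.18. The fatty acid score was 0.16 in replicates 2, 3, 5 and 6 and 0.14 in replicate 4, both within the control range of -0.22 to 0.21. The fatty acid synthesis call was lost without control replicates 1 and 3 (adjusted p = 0.187), control replicate 5 (0.396), 1.0% replicates 2, 3, 5 and 6 (0.217) or 1.0% replicate 4 (0.0632). When each array was centred on its median, neither call held (adjusted p = 0.0880 and 0.493), and the median of all genes then lay at -0.20 in this comparison. Neither held without scaling, and the fatty acid call was also lost without the filter.

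Genes of PPARA-driven fatty acid oxidation fell as a group at 1.0%, with 22 of 26 lower and a median of -0.17 (camera adjusted p = 0.00195; adjusted p = 0.66 with an estimated correlation; 3.3e-05 to 0.66 across alternatives). None was called over all genes or when adjusted over the list alone. Examples were Acaa1b, a peroxisomal thiolase, at -0.40 ± 0.11, Acot1 at -0.87 ± 0.35 and Creb3l3 at -0.29 ± 0.09. The PPARA score was -0.31 in replicates 2, 3, 5 and 6 and -0.10 in replicate 4, where control samples ran from -0.05 to 0.08. The call was lost without replicates 2, 3, 5 and 6 (adjusted p = 0.434). Genes of the unfolded protein and ATF4 response rose as a group, with 15 of 23 higher and a median of 0.18 (camera adjusted p = 0.0453; adjusted p = 0.66 with an estimated correlation; 0.00053 to 0.85 across alternatives). None of these passed over all genes or when adjusted over the list alone. The endoplasmic reticulum chaperone Hyou1 stood at 0.70 ± 0.19, Creld2 at 1.11 ± 0.40 and Manf at 0.48 ± 0.17. The unfolded protein score was 0.22 in replicates 2, 3, 5 and 6, above the control range of -0.14 to 0.19. In replicate 4 it was -0.02, within that range, so the rise rests on the RNA of replicates 2, 3, 5 and 6. That call was lost without control replicates 1 and 3 (adjusted p = 0.214) or 2 and 4 (0.121), either 0.5% sample (0.0559 without replicates 1, 2, 3 and 6, 0.0553 without 4 and 5) or 1.0% replicates 2, 3, 5 and 6 (0.847). It was also lost with arrays centred on their medians (0.289), without scaling (0.648), without the filter (0.104) and with 15 samples (0.0623). Heat shock genes had no common direction (camera adjusted p = 0.990), but when adjusted over the list alone the inducible chaperones Hspa1a (-1.91 ± 0.58) and Hspa1b (-1.94 ± 0.55) fell and Hsp90aa1 (1.06 ± 0.32) rose. Hspa1a and Hspa1b are near-identical copies, so their probe sets are not independent. Igfbp1, an insulin-repressed binding protein, fell (-1.69 ± 0.43) when adjusted over its list alone, with an adjusted p of 0.63 over all genes.

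Clec2d, a lectin-like ligand of an NK cell receptor, rose 2.85-fold at 1.0%, from 6.00 ± 0.16 (SD, n = 4) to 7.52 ± 0.08 (SD, n = 2; limma adjusted p = 0.0310). Rbmxl2 fell from 5.09 ± 0.41 to 3.07 ± 0.09, near the floor (adjusted p = 0.0347). These were the 2 genes called, beside 853 with an unadjusted p under 0.05. When a sample was left out, Clec2d was kept only without 0.1% replicate 4 or 5 and Rbmxl2 only without control replicate 5 or 0.1% replicate 5, with adjusted p up to 0.676 for both. Of the other settings, 5 of 16 ended the Clec2d call and 6 of 15 the Rbmxl2 call at 1.0% (adjusted p up to 0.703 for Rbmxl2). The Gapdh and actin differences at 1.0% were -0.35 ± 0.01 and 1.35 ± 0.17, with exact permutation p-values of 0.733 and 0.667 against control. The log2 ratio of poly-A to hybridisation controls was 0.40 ± 0.33 in control liver and -0.88 ± 1.21 at 1.0% (exact permutation p = 0.0667, the smallest that 15 splits allow), and 0.81 ± 0.07 and -0.24 ± 0.36 at 0.1% and 0.5% (0.114 and 0.133).

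Across the doses, the slope on phloridzin content called 0 genes in limma (smallest adjusted p = 0.169), beside 1153 with an unadjusted p under 0.05. The 6 genes with the lowest p were Rbmxl2, Scara5, Brms1, Ccl9, Atp5d and Rab40c. Scara5, a ferritin receptor, had a slope of 1.41 ± 0.24 (SE) per 1% of diet and Ccl9, a chemokine, 0.51 ± 0.10, neither past the threshold (adjusted p = 0.216 and 0.357). As groups, cholesterol synthesis and acute phase genes had a positive slope on dose and PPARA oxidation genes a negative one (camera adjusted p = 0.0316, 0.0244 and 0.0244), each with an adjusted p = 0.93 with an estimated correlation, the highest across alternatives. The lowest were 0.00078, 2.1e-06 and 0.00097. The rise was not steady: the median for cholesterol synthesis was 0.13, 0.02 and 0.17 at 0.1, 0.5 and 1.0%, and for acute phase genes -0.02, 0.28 and 0.10. Within the PPARA list Acaa1b and Creb3l3 fell with dose when adjusted over the list alone, as did Nr0b2 (-0.88 ± 0.23) within the bile acid list. Over the unfolded protein list alone Hsp90b1, Dnajc3 and Hyou1 rose with dose and Dnajb9 fell. Over the heat shock list alone Hsp90aa1 rose and Hspa1a, Hspa1b, Dnajb1 and Hspb8 fell. Neither list shifted as a group on the slope (camera adjusted p = 0.214 and 0.972). No list call on the slope was kept without 1.0% replicates 2, 3, 5 and 6 (adjusted p = 0.116, 0.0985 and 0.503 for cholesterol, acute phase and PPARA). The cholesterol slope was also lost without control replicates 1 and 3 (0.280), control replicate 5 (0.193) or 1.0% replicate 4 (0.250), the acute phase slope without control replicate 6 (0.0502) or 0.5% replicates 1, 2, 3 and 6 (0.0872), and the PPARA slope without control replicate 6 (0.0502). The cholesterol slope was also lost with arrays centred on their medians (0.485), without scaling (0.568) and without the filter (0.110), and the acute phase slope without the filter and with 15 samples.

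Between doses, limma called 2 genes at 1.0% against 0.1%, Nsd3, a histone methyltransferase (1.52 ± 0.21), and Rbmxl2 (adjusted p = 0.0480 for both), and 0 genes at 0.5% against 0.1% (1393 with an unadjusted p under 0.05) or at 1.0% against 0.5% (548). At 1.0% against 0.1% the count was 0 in 7 of the 11 runs that left out a sample, and without the joining of RNA by fingerprint it was 143, with 39 at 0.5% against 0.1%. The count at 0.5% against 0.1% was 22 with 15 samples and 7 without 0.5% replicates 4 and 5. Dusp1 and Clec2d were not called between any pair of doses. At 1.0% against 0.1% the adjusted p was 0.063 for Dusp1, and at 1.0% against 0.5% it was 0.30 for Clec2d. Log2 changes against control correlated across genes at r = 0.455 for 0.5% with 1.0%, 0.218 for 0.1% with 0.5% and 0.223 for 0.1% with 1.0%. Unchanged groups simulated against the same controls gave 0.335, 0.380 and 0.379. In the same order, the covariance minus the simulated one was 0.0114, -0.00993 and -0.00855, and with separate controls for each dose, split 2 and 2, the correlations were 0.153, -0.0410 and -0.0258. The simulation used the same spread of a gene in every diet, pooled over the diets, and drew genes independently. The negative differences therefore need not mean that effects were less alike than in unchanged groups. Rbmxl2, lower at both 0.5% and 1.0%, was the 1 call shared between doses, and both calls rest on the same control samples.

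Of glucose handling, the subject of the series title, no member of the gluconeogenesis, glycolysis or glycogen metabolism lists was called against control or on the slope, and Gsk3a, called at 0.1%, is on none of these lists. Pck1, the gluconeogenic carboxykinase, was 11.33 ± 0.23 in control liver and 11.34 ± 0.25, 10.96 ± 0.36 and 11.41 ± 0.36 at 0.1, 0.5 and 1.0%. The glucose transporter Slc2a2 was 11.38 ± 0.15 in control liver and 11.38 ± 0.01 at 1.0%, and G6pc, the glucose-6-phosphatase, was 11.07 ± 0.12 in control liver and 10.46 ± 0.71, 10.88 ± 0.36 and 10.72 ± 0.72 at the 3 doses. Srebf1 differed by -0.30 ± 0.19 and Fgf21 by -0.30 ± 0.30 at 1.0%. Pklr, liver pyruvate kinase, rose at 0.1% when adjusted over the glycolysis list alone (0.53 ± 0.13; adjusted p = 0.47 over all genes), though its 2 other probe sets stood at 0.13 and 0.05. Tat fell at 0.5% when adjusted over the gluconeogenesis list alone (-0.49 ± 0.13). The lowest camera adjusted p over the 3 doses was 0.308 for gluconeogenesis (0.5%, median -0.09), 0.685 for glycolysis (0.1%, 0.05), 0.726 for glycogen metabolism (1.0%, -0.10) and 0.0554 for the fasting and FOXO response (0.5%, -0.22). Of the clock genes in the panel, none called, Arntl was 6.37 ± 0.36 in control liver and 6.92 ± 0.20 at 0.5%, and Per2 6.28 ± 0.27 and 5.72 ± 1.05.

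Of the 31 lists tested, 22 were called in no comparison against control. The lowest adjusted p over the doses was 0.0521 for both male-biased liver genes (1.0%, median 0.18) and CAR/PXR targets (1.0%, -0.17), 0.0707 for pericentral genes (0.5%, -0.13), 0.0966 for heat shock chaperones (0.5%, -0.15) and 0.108 for sinusoidal endothelial markers (0.1%, -0.13). It was 0.163 for immediate early genes, 0.173 for periportal genes, 0.182 for cholangiocyte markers, 0.286 for the circadian clock, 0.362 for both cell cycle genes and erythroid markers and 0.422 for female-biased genes. For B and plasma cell markers, AhR targets, T and NK cell markers, bile acid transport, interferon response and stellate cell markers it was 0.511, 0.518, 0.532, 0.532, 0.533 and 0.738. With an estimated correlation or with the directional test of fry, 0 of the 31 lists were called in any comparison. The mixed test of fry, which counts changes in either direction, gave an adjusted p of 0.0233 for immediate early genes and 0.0438 for Kupffer markers at 0.1%, 1.5e-05 for NRF2 genes at 0.5%, 0.00858 for female-biased genes at 1.0% and 0.0464 for the unfolded protein response on the slope.

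**Figure D3:**
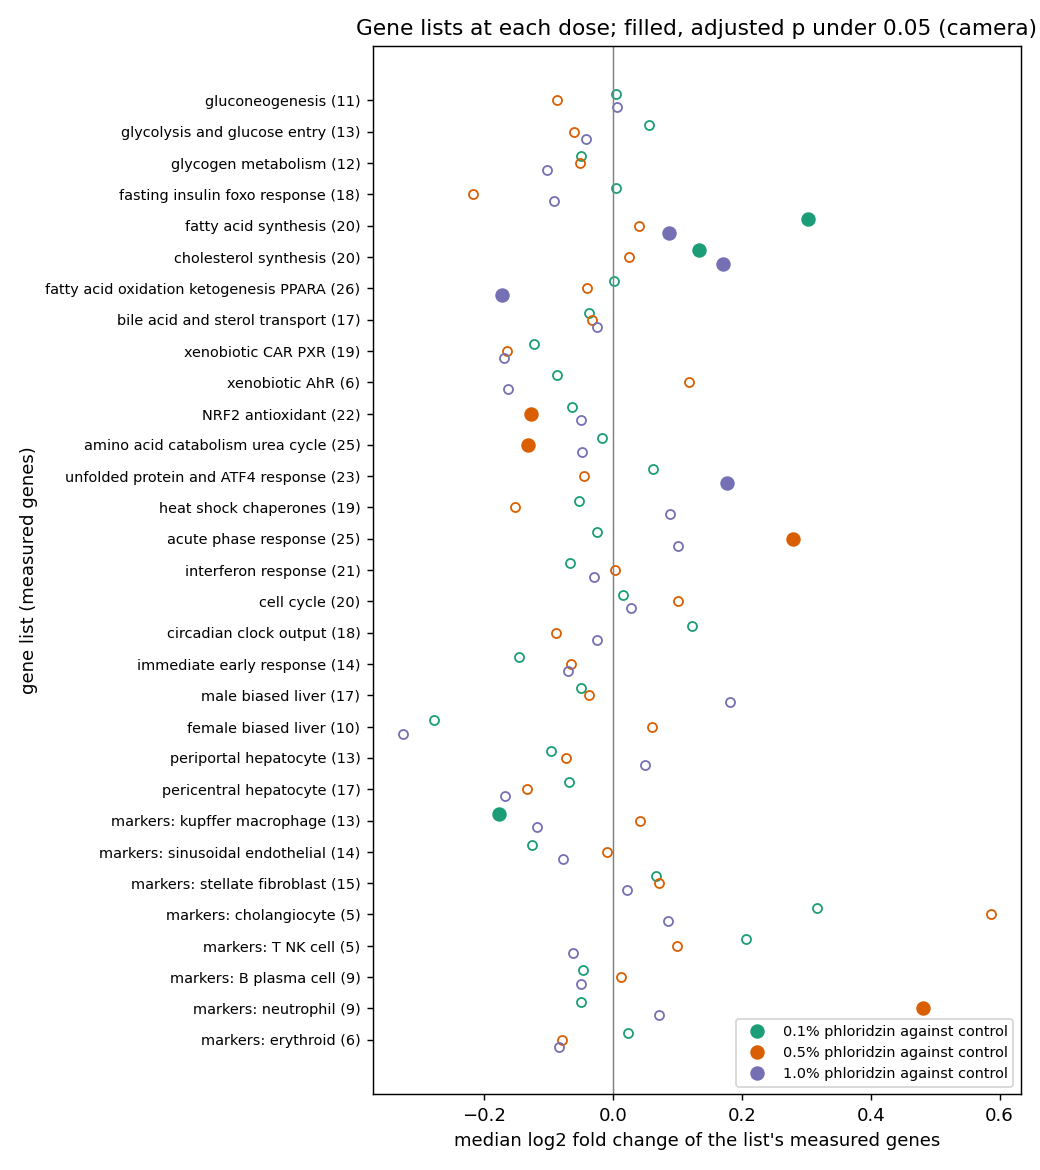
Each point is the median log2 fold change of a list's measured genes (number in brackets) at 0.1, 0.5 or 1.0% phloridzin against control, filled where the camera adjusted p was under 0.05 at the preset correlation. Fatty acid synthesis lay highest at 0.1% among the called lists of that dose (0.30), acute phase genes and neutrophil markers were called at 0.5% (0.28 and 0.48), and PPARA oxidation genes were called at 1.0% (-0.17).

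**Figure D4:**
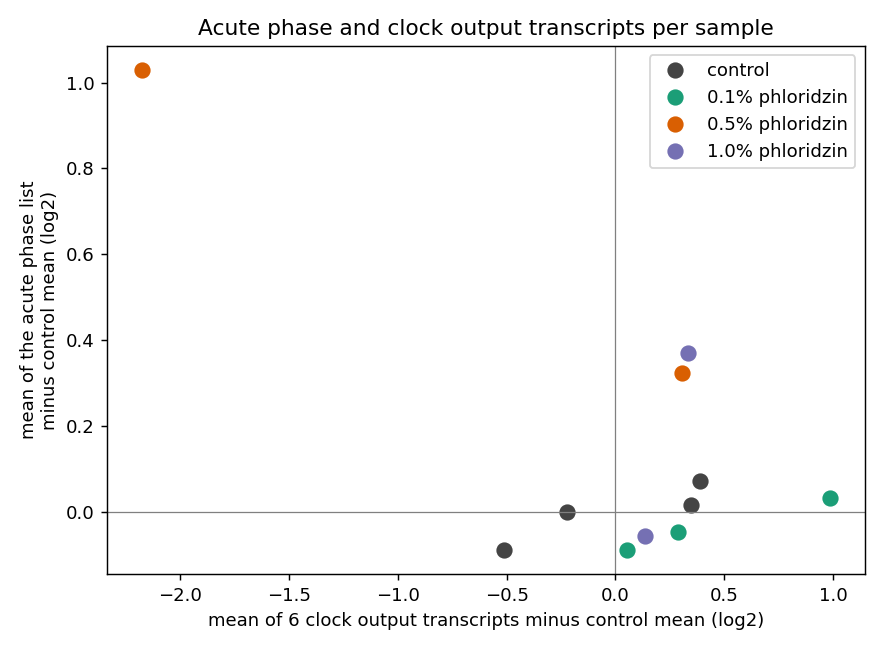
Each point is 1 RNA sample, with the mean log2 signal of 6 clock output transcripts on the horizontal axis and of the acute phase list on the vertical axis, both minus the control mean. The RNA of 0.5% replicates 1, 2, 3 and 6 lay at -2.18 and 1.03, and 2 other phloridzin samples lay at acute phase scores of 0.32 and 0.37, above the highest control at 0.07.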

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

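The tests on near-identical arrays, clock output and acute phase transcripts were chosen only after these results were seen, while the counts over regrouped samples at 0.1% were planned.

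Near-identical arrays stood apart from all others, although the labels describe 6 mice per diet. A copied table is excluded, since at most 1 value was identical in any repeat pair. Separate cage-mates that resemble each other cannot alone make the largest set, 4 arrays with labels of 2 diets where a cage held 3 mice. They stay open for its arrays of 0.1% replicates 1, 3 and 6, should 1.0% replicate 1 hold a wrong RNA or label. Cage-mates stay open for the other sets too. There the lowest SD of all other pairs of a diet was 1.87 times the highest of the repeat pairs (0.0577). Without pairs read as 1 RNA by fingerprint the lowest was 0.164, but both kinds of pair were themselves picked by low distances. Repeat hybridisation of 1 labelled RNA could account for the sets: the log2 ratio of poly-A to hybridisation controls, set while an RNA is labelled, differed by a median of 0.0268 within repeat pairs against 0.393 between other arrays of a diet. The array of 1.0% replicate 1 differed from 0.1% replicates 1, 3 and 6 by an SD of at most 0.0538, and from the other 1.0% arrays by 0.511 or more, which a wrong RNA or a wrong label for an array could produce. The nearest array outside that set was 0.1% replicate 5 (0.222), and 0.1% replicates 2 and 4 (0.368 and 0.432) also lay nearer than any other 1.0% array. Between the 2 labels, these distances favour 0.1%. They do not settle which label is right, since control replicates 5 and 6 (0.379 and 0.363) lay about as near, so nearness did not follow diet.

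Acute phase transcripts were high in 3 of the 4 samples at 0.5% and 1.0% (scores of 1.03, 0.32 and 0.37, against a highest control of 0.07; the other, 1.0% replicate 4, at -0.06). In the first of these, clock output was low and the transcripts of the opposite arm were high, at 0.46 against a highest control of 0.26, so that a different time of killing is a possible explanation for the clock genes. Time of killing is unlikely as the whole cause of the acute phase values, since the clock output of 0.5% replicates 4 and 5 was 0.30, within the control range. Blood neutrophils stay open for 0.5% replicates 4 and 5, with a marker score of 0.79 against a highest control of 0.18. They also stay open for 1.0% replicates 2, 3, 5 and 6 (0.35 in replicates 2 and 3, -0.10 in 5 and 6, arrays read as the same RNA). The sample with the highest acute phase score stood at 0.10, below the highest control but by less than such labellings differ. A marker score speaks to the presence of neutrophils, not to whether they carry acute phase transcripts, so it cannot decide this. A response to phloridzin at 0.5% or more stays open too: the exact permutation p of 0.0182 (4 samples against 7, 330 splits, smallest possible 0.00303) is for a grouping drawn after the high samples were seen, so it decides nothing.

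When the 7 samples of control and 0.1% liver were regrouped in every way, 2 of the 35 splits, the real one included, gave as many called genes as the 3 observed (highest other 9), and 17 gave as many shifted lists (real 3, highest other 5). Chance could therefore produce the counts at 0.1%, and the list count in particular is no larger than regrouping gives. With 7 samples the test has little power.

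Among 181 values tested in the 4 control samples, 15 (8.29%) had a sample far from the others, where chance alone gives about 1 in 20. Control replicate 6 was high for Acaa1b (13.01), Dhcr7 (8.79), Gyg (7.37), Ltf (3.67) and the gluconeogenesis score (0.12), and low for Slc40a1 (10.50). Control replicate 5 was low for Epcam (3.00, the floor), G6pc (10.89), Khk (10.96) and Oasl2 (3.55). Control replicates 2 and 4 were high for Dusp1 (10.78), Fabp4 (7.06) and the Kupffer score (0.094) and low for Il7r (3.01), and control replicates 1 and 3 were low for Col1a1 (3.96). In the RNA with labels of different diets, which no comparison uses, the log2 ratio of poly-A to hybridisation controls was 1.14 to 1.23, above the highest control array at 0.70.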

How the results depend on the processing

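Most alternatives were planned, while no scaling between arrays, all 24 arrays, the block on 24 arrays, 13 samples, 15 samples, the 2 and 2 split of controls and the runs without a sample for lists were chosen only after seeing the data. No named gene called against control, and no called list, turned its direction. For results not called, a turn of direction was counted as moved without a look at the threshold. Requiring a log2 change of 0.5 or more (run on 6 counts) and dropping probe sets marked x, s or a (8 counts) left those counts within 1.5 times their values, though the latter moved 21 values of named genes. The slopes on the rank of the dose and within phloridzin-fed mice called 0 genes. The counts of called genes given above are 3 at 0.1%, 1 at 0.5% and 2 at 1.0% against control, 2 at 1.0% against 0.1%, 0 at 0.5% against 0.1%, 0 at 1.0% against 0.5%, 0 on the slope and 2 for any difference among diets, and those of lists are 3, 4, 4 and 3 for the 3 doses and the slope. With counts this low a single gene moves them, and unless stated the cause was not tested.

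Centring arrays on their medians gave 1 gene at 0.1% (0 higher, 1 lower, against 1 and 2), 3 at 0.5% (0 higher, 3 lower), 0 at 1.0%, 0 at 1.0% against 0.1% and 1 list at 1.0%. No scaling gave 0 genes at 0.1%, 2 at 0.5% (1 higher, 1 lower), 1 at 1.0% (0 higher, 1 lower), 0 at 1.0% against 0.1%, 4 at 0.5% against 0.1%, 1 on the slope, 1 for any difference, 10 lists at 0.5% and 6 on the slope. The median log2 change of all genes at 0.1, 0.5 and 1.0% was then -0.16, -0.19 and -0.35, and with arrays centred on their medians -0.08, -0.09 and -0.20. Without the filter there were 1, 4, 1 and 3 genes at 0.1%, at 0.5%, at 1.0% against 0.1% and at 0.5% against 0.1%, 1 on the slope, 4 for any difference, 2 lists at 1.0% and 1 on the slope. Leaving out the lowest 60% gave 0 genes at 0.5%, 1 at 1.0%, 0 at 1.0% against 0.1% and 0 for any difference. A floor 4 times higher gave 0 genes at 0.1%, 6 at 1.0%, 5 at 1.0% against 0.5%, 7 at 1.0% against 0.1%, 2 at 0.5% against 0.1%, 2 on the slope and 7 for any difference, and 4 times lower 1 at 0.1% and 1 at 0.5% against 0.1%. No detection calls came with the signals, so signal near background is limited only by this floor, and dim genes such as Rbmxl2 depend on it by construction.

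Without the mean-variance trend there were 0 genes at each of 0.1%, 0.5%, 1.0% and 1.0% against 0.1%, 2 at 0.5% against 0.1% and 1 for any difference. Robust variance gave 0 at 0.5% and 4 for any difference, array weights 0 at 1.0% against 0.1% and 2 at 1.0% against 0.5%, and fits of only the diets compared 1 at 0.1%, 1 at 1.0% and 0 at 1.0% against 0.1%. All probe sets gave 1 at 0.1% and 0 at 0.5%, 1.0% and 1.0% against 0.1%, the mean of probe sets 0 at 1.0% against 0.1% and 1 at 0.5% against 0.1%. An adjusted p under 0.01 left 0 genes at 0.1%, 0.5%, 1.0%, 1.0% against 0.1% and for any difference, by construction. An estimated correlation gave 0, 0, 0 and 0 lists at the doses and on the slope, and the directional test of fry 0, 0, 0 and 0.

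Keeping RNA joined by fingerprint apart (13 samples) gave 17 genes at 0.5%, 6 at 1.0% against 0.5%, 143 at 1.0% against 0.1%, 39 at 0.5% against 0.1%, 4 on the slope, 30 for any difference and 5 lists on the slope. Keeping that RNA apart and also the RNA with labels of different diets under both labels (15 samples), which changes 2 choices together, gave 0 genes at 0.1%, 1.0%, 1.0% against 0.1% and for any difference, 22 at 0.5% against 0.1%, 7 lists at 0.5%, and correlations of 0.511 for 0.1% with 1.0% and 0.391 for 0.5% with 1.0%; the shared RNA enters both doses there. All 24 arrays as separate samples gave 2605, 444 and 396 genes at 0.1, 0.5 and 1.0%, 966 at 1.0% against 0.5%, 2115 at 1.0% against 0.1%, 3966 at 0.5% against 0.1%, 110 on the slope, 4663 for any difference, 5 lists on the slope and a correlation of 0.441 for 0.1% with 1.0%. By construction repeat arrays count there as mice. Controls split 2 and 2 gave correlations of -0.0410, -0.0258 and 0.153 for 0.1% with 0.5%, 0.1% with 1.0% and 0.5% with 1.0%. A split of 3 and 3 was not run, as it needs 6 control samples.

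The replicate number as a block could not be fitted to averaged samples and was run on 24 arrays, where it gave 2705, 411 and 378 genes at the 3 doses, 936 at 1.0% against 0.5%, 2182 at 1.0% against 0.1%, 3983 at 0.5% against 0.1%, 18 on the slope and 4672 for any difference, close to the values without the block on the same arrays except on the slope. In the check of pairing, 6 of 36 same-number pairs correlated over 0.1 (median -0.00512) and 4 of 24 arrays matched their own number best, so the numbers do not pair the samples.

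Leaving out each of the 11 samples in turn, where a lone sample is assumed to vary like the other groups, gave 0 to 2 genes at 0.1%, 0 to 8 at 0.5%, 0 to 2 at 1.0%, 0 to 3 at 1.0% against 0.5%, 0 to 3 at 1.0% against 0.1%, 0 to 7 at 0.5% against 0.1%, 0 to 1 on the slope and 0 to 6 for any difference. Lists ran from 2 to 4, 2 to 10 and 2 to 5 at the doses and 0 to 3 on the slope. The correlations ran from 0.108 to 0.310, 0.0999 to 0.336 and 0.357 to 0.536 for 0.1% with 0.5%, 0.1% with 1.0% and 0.5% with 1.0%.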

Other observations

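No test was added for this part, and the values below were picked after they had been seen.

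Some liver genes outside the groups described above passed when adjusted over their list alone, at the doses given here, and none of them passed over all genes. At 1.0%, Mup3, a male-typical urinary protein, rose (0.37 ± 0.10, log2 change ± SE) and Cyp2b9, a female-typical cytochrome, fell (-1.31 ± 0.37) when adjusted over their lists alone. At 0.5%, Nr1d1, a repressor in the clock, fell when adjusted over its list alone (-2.06 ± 0.43), and so did the immediate early genes Junb (-1.02) and Zfp36 (-0.88) and the erythroid enzyme Alas2 (-0.69 ± 0.14). Dusp1, described above at 0.1%, fell at 0.5% over the immediate early list alone as well (-0.86). The samples at 0.5% differed in their clock genes, with output scores of -2.18 in replicates 1, 2, 3 and 6 and 0.30 in replicates 4 and 5. The replication factor Mcm2 rose at 0.5% over its list alone (1.33 ± 0.32), with its other probe set at 0.05. At 0.1%, Per1, a clock repressor, rose (1.54 ± 0.37) when adjusted over its list alone. In 0.1% replicate 2 the clock output score was 0.99, above the highest control at 0.39, and that of the opposite arm -0.70, below the lowest control at -0.28, while the output scores of 0.1% replicates 4 and 5 were 0.05 and 0.29.

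In the RNA labelled 0.1% replicates 1, 3 and 6 and, on another array, 1.0% replicate 1, the log2 signal was 8.83 and 8.76 for Dusp1, 10.16 and 10.19 for Zfp36l1, 8.36 and 8.26 for Gsk3a, 5.96 and 6.12 for Clec2d, 3.26 and 3.69 for Rbmxl2, and 7.40 and 7.57 for Saa2. Acss2 was 10.06 and 10.05 and Vsig4 8.02 and 8.05.

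Markers of tissues that border the liver had too few measured members for a list test. In control liver and at 1.0%, Cela1, Cela3b and Prss2 of the pancreatic list were 9.80 ± 0.16 and 9.85 ± 0.01, 4.83 ± 0.29 and 4.90 ± 0.09, and 4.17 ± 0.62 and 4.41 ± 0.18 (SD). At 0.1% and 0.5%, Cela1 was 9.60 ± 0.06 and 9.56 ± 0.14, Cela3b 5.24 ± 0.31 and 5.18 ± 0.11, and Prss2 4.74 ± 0.57 and 4.54 ± 0.83. Car3 and Fabp4 of the adipocyte list were 13.66 ± 0.02 and 13.68 ± 0.00, and 6.78 ± 0.19 and 6.67 ± 0.05, in control liver and at 1.0%. Dimmer probe sets of Car3, not tested, differed by 1.30 and 1.98 at 1.0%. Cela1 and Car3 were far brighter than the other members of their lists, and whether they report bordering tissue was not tested. Pnpla2 was 7.46 ± 0.19 in control liver and 7.86 ± 0.25 at 0.1%, with a dimmer probe set at -0.20 there. The muscle transcript Ckm was 3.82 ± 0.54 in control liver and 4.17 ± 0.43, 4.01 ± 0.42 and 3.89 ± 0.85 at 0.1, 0.5 and 1.0%, and Pvalb was 3.28 ± 0.48, 3.83 ± 0.03 and 3.62 ± 0.31 at these doses.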
